A study of Drosophila melanogaster with 14 samples.

How the data were processed

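RNA sequencing of cultured Drosophila melanogaster ovarian somatic cells was analysed in 8 libraries, 2 each after 48 hours of RNAi against EGFP (the control), l(3)mbt, Lint-1 and the gene of Lint-O. Per the labels' protocols, polyadenylated RNA was selected and stranded mRNA libraries were prepared. The deposited table held raw read counts per gene, which per the submitters' processing notes came from a workflow that names HISAT2, HTSeq and edgeR and the genome build dm6. The roles and versions of these tools, the annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. The 4 ChIP and 2 input samples of the 14 in the series were not analysed here.

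The table had 16732 entries, of which 16727 were genes and 5 were the counter's special lines, 3 of them at 0 in every library. The special lines stayed out of library sizes and tests. Reads without a gene made up 14.96% to 18.51% of a library, and ambiguous reads 1.05% to 1.13%. Reads on genes ranged from 18293791 to 20978039 per library, and 9156 to 9756 genes had a count. The 10 most abundant genes took 6.38% to 7.38% of the reads. A count of 0 allows up to 3 counts, 0.143 to 0.164 CPM depending on the library. Floors and counting intervals (95%, exact) cover counting error only, because the reads carry no molecular identifiers.

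Symbols were looked up in the RefSeq gene table of the same assembly (dm6). Of them 12512 were current, 3933 matched through a synonym and 282 matched no single gene, among them nos, for which no position is given. CG2662 matched the current symbol Lint-O. Positions and spans are of the whole gene in that table. Of 367 list entries typed by symbol, 32 were found under another name and 2 (solo and rye) had no line in the table.

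Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr by group, TMM factors (0.948 to 1.056), glmQLFit over all 8 libraries with group as the only term (4 residual degrees of freedom), and glmQLFTest for 6 contrasts, namely each knockdown against the control and the 3 pairs of knockdowns. Of 8244 tested genes, those with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 15.43% and the median prior degrees of freedom 5.024. Genes with no count in the control are given as at least the fold over a floor of 3 counts per library, and genes with 1 to 3 counts as a ratio with its counting interval. Groups of 2 allow neither a test of other splits of the samples nor a search for single outlying values. Counts of the 2 libraries of each group differed beyond sampling noise (chi-square per degree of freedom 22.64 to 54.26), so each was treated as a separate library.

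The tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists were drawn from general knowledge of the tissue and the pathway, and the germline, testis and piRNA lists hold gene classes that earlier work on l(3)mbt mutants had pointed to, so they are not independent of that work. The rule named, for each knockdown against the control, the 3 RNAi targets, every tested piRNA amplification factor, and the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and both knockdown libraries on the same side of both control libraries. It also named up to 3 called members of each other list. Between knockdowns it named the targets and the 5 largest rises and falls. Some were left out for space, and members named only as part of a list's count carry no values. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log CPM with a prior count of 3 and a preset correlation of 0.01, two-sided, adjusted over the lists within a comparison.

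Overlaps were set beside those of independent lists and of 50 simulations in which all 8 libraries, the control included, were drawn from the control means. The procedure was tested on simulated counts for L(3)mbt KD against EGFP KD over 8093 genes. edgeR recovered 81 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, with 12 false calls (6.383% of its calls). DESeq2 recovered 86 and 94, with 30 false calls (14.29%). A comparison without changes gave 0 calls in edgeR and was not run with DESeq2.

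The alternatives tried were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter one (at least 1 CPM in 2 libraries and 50 counts in total), a fit of only the 4 libraries compared, the replicate number as a block, at least a 2-fold change, and each library left out in turn. For lists, an estimated correlation and the fry test were tried. A crossed replicate block, the removal of a lowess trend (span 0.3) of each library against log2 gene span, and a split of the control libraries between the knockdowns of a pair were chosen after seeing the data. Of the tested genes 8144 (98.79%) had a span. GC content was not examined because no genome sequence was used here.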

Results

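Polyadenylated RNA was sequenced from cultured Drosophila melanogaster ovarian somatic cells, a line of follicle-cell origin that runs a somatic form of the piRNA pathway. The cells had been treated for 48 hours with RNAi against EGFP, a sequence fly cells lack and here the control, or against 1 of 3 genes. These were l(3)mbt, which encodes a chromatin protein with malignant brain tumour repeats, and the genes of the L(3)mbt interactors Lint-1 and Lint-O. Each of the 4 groups had 2 libraries. Reads assigned to genes came to 18721044 and 19512731 in the EGFP knockdown (EGFP KD), and to 18293791 and 19738751 in L(3)mbt KD. They came to 20978039 and 18669633 in Lint-1 KD and to 20129922 and 18766301 in Lint-O KD. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are TMM-normalised CPM, given as mean ± SD with n = 2. Adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named. The 6 ChIP and input samples of the series were not analysed here.

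The RNAi targets were examined first. The l(3)mbt transcript (dm6, 3R, 27266326 to 27273273) stood at 186.5 ± 1.13 CPM in EGFP KD and 99.3 ± 4.79 CPM in L(3)mbt KD, a log2 fold change of -0.91 (SE 0.102, edgeR adjusted p = 0.000439). Lint-1 (X, 11149323 to 11152592) fell from 54.4 ± 4.54 to 10.98 ± 1.65 CPM in Lint-1 KD, a log2 fold change of -2.31 (SE 0.164, edgeR adjusted p = 3.83e-05). Lint-O, listed as CG2662 (X, 2698701 to 2701033), fell from 19.0 ± 1.31 to 1.57 ± 0.594 CPM in Lint-O KD, a log2 fold change of -3.59 (SE 0.263, edgeR adjusted p = 7.76e-05). Each target was therefore lower in both libraries that carry its label. The mRNA of the other targets did not pass the test in any knockdown. The nearest to it was Lint-1 in L(3)mbt KD, at 79.0 ± 9.72 CPM (log2 fold change 0.54, SE 0.152, edgeR adjusted p = 0.0547). That value passed with upper-quartile scaling (0.0494), with DESeq2 (0.0332), without the low-count filter (0.0437), with the gene-span trend removed (0.0255) and without L(3)mbt KD 1 (0.0350). In Lint-O KD Lint-1 stood at 77.8 ± 0.377 CPM (edgeR adjusted p = 0.114). Adjusted over the 3 targets alone, Lint-1 was higher in L(3)mbt KD and both Lint-1 and l(3)mbt in Lint-O KD.

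**Figure D1:**
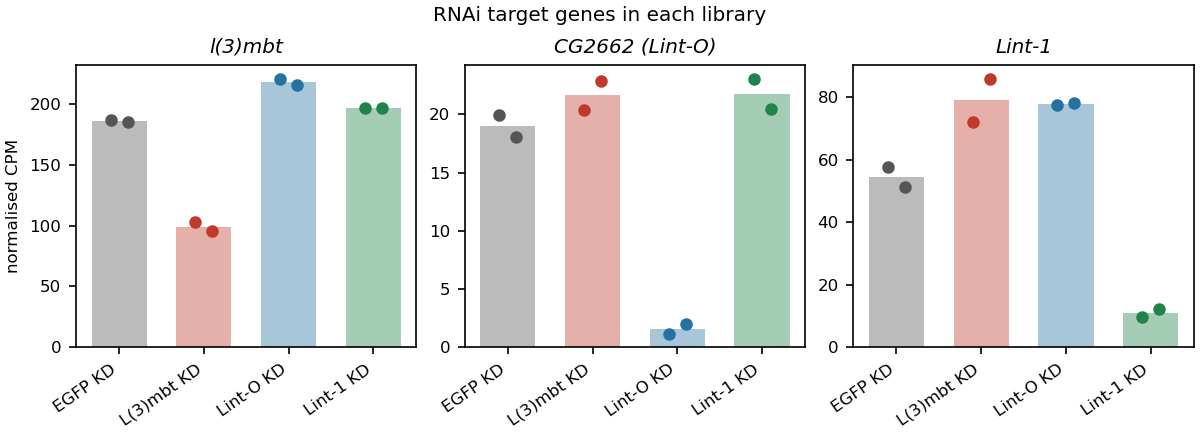
Normalised CPM (linear axis from 0) of l(3)mbt, Lint-1 and CG2662 (Lint-O) in the 4 knockdown groups; bars are means of 2 libraries and dots are single libraries. Each transcript was lowest in the knockdown directed against it: l(3)mbt at 99.3, Lint-1 at 10.98 and CG2662 at 1.57 CPM.

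The comparison of L(3)mbt KD with EGFP KD asks which transcripts depend on L(3)mbt in these cells. Among the genes that rose were germline genes with low levels in the control. The vasa transcript (vas, 2L, 15061656 to 15074311), for the DEAD-box helicase of the germline perinuclear granules called nuage, rose from 1.40 ± 0.215 to 123.5 ± 1.86 CPM (log2 fold change 6.46, SE 0.218, edgeR adjusted p = 2.17e-06). The aub transcript (2L, 10997819 to 11001476), for a PIWI protein of the germline ping-pong cycle that amplifies piRNAs, rose from 2.64 ± 0.526 to 45.0 ± 0.42 CPM (4.08, SE 0.199, edgeR adjusted p = 7.63e-06). The synaptonemal complex gene cona (3R, 18385828 to 18386887) rose from 0.267 ± 0.0638 to 105.3 ± 17.4 CPM (8.58, SE 0.380, edgeR adjusted p = 6.1e-06). vas shares exons with solo, so some of its reads could belong to that gene.

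Among 12 germline piRNA amplification factors, 6 rose and 6 did not pass, with the same 6 rises when adjusted over the list alone. Besides vas and aub, AGO3, the other PIWI protein of the ping-pong cycle, rose from 2.14 ± 0.131 to 9.16 ± 0.515 CPM (log2 fold change 2.09, SE 0.267, edgeR adjusted p = 0.000958). The Tudor-domain gene qin rose from 2.51 ± 0.418 to 13.6 ± 7.25 CPM (2.43, SE 0.415, edgeR adjusted p = 0.00511). Another Tudor-domain gene, tej, had 2 counts in the control libraries together and reached 2.19 ± 1.05 CPM, a ratio of 40.9 with a 95% counting interval of 10.97 to 343.0 (edgeR adjusted p = 0.00351). CG9925 (Kots), with no count in the control, was at least 12.2-fold higher at 1.96 ± 0.301 CPM (edgeR adjusted p = 0.00215). The remaining members were already expressed in the control. spn-E stood at 184.8 ± 27.5 and 172.4 ± 47.6 CPM in EGFP KD and L(3)mbt KD, and krimp at 116.2 ± 15.7 and 89.4 ± 41.1. In the same order CG8920 (tapas) stood at 73.0 ± 3.95 and 73.9 ± 14.9, tud at 34.98 ± 13.3 and 29.5 ± 14.4, BoYb at 30.1 ± 1.22 and 22.7 ± 2.69, and squ at 16.6 ± 3.69 and 19.7 ± 0.197. The list as a whole was higher than other genes (camera adjusted p = 0.00349), but not with an estimated inter-gene correlation (adjusted p = 0.684 with an estimated correlation). Without L(3)mbt KD 1 krimp fell past the threshold (log2 fold change -0.96, adjusted p = 0.0263).

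**Figure D2:**
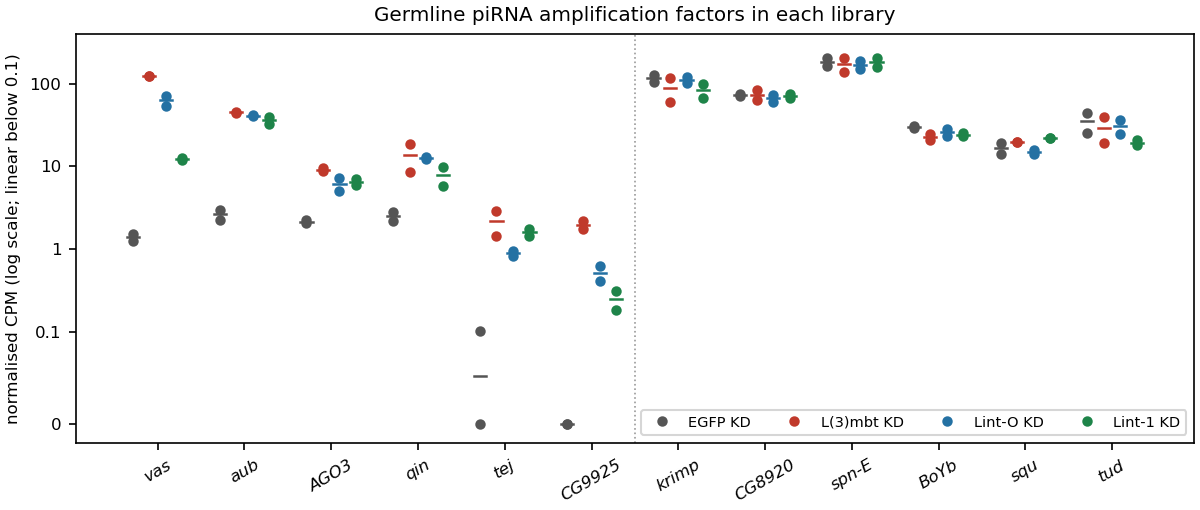
Normalised CPM of the 12 germline piRNA amplification factors in the 4 groups, on a symmetric log axis that is linear below 0.1; dots are single libraries and short bars are group means. Left of the dotted line are the 6 genes called higher in at least 1 knockdown, with vas going from 1.40 CPM in EGFP KD to 123.5, 63.1 and 12.3 CPM in L(3)mbt, Lint-O and Lint-1 KD, and right of it are the 6 that did not pass in any.

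Of 18 tested germline identity and oogenesis genes, 10 rose and 8 did not pass, while 13 rose when adjusted over the list alone (camera adjusted p = 7.1e-09, and adjusted p = 0.194 with an estimated correlation). The 10 were alphaTub67C, bgcn, exu, gnu, nos, ovo, png, Pxt, Rbp9 and swa. bgcn, a partner of the differentiation factor bam, rose from 2.37 ± 0.766 to 20.6 ± 4.36 CPM (log2 fold change 3.11, SE 0.271, edgeR adjusted p = 0.000102). nos, a translational repressor of the germline, went from 2 counts in the control to 3.95 ± 0.603 CPM, a ratio of 73.6 (95% counting interval 20.03 to 613.1, edgeR adjusted p = 0.000439). swa, which acts in RNA localisation in the oocyte, had no count in the control and was at least 56.2-fold higher at 9.06 ± 0.434 CPM (edgeR adjusted p = 6.73e-05). Of 19 meiosis genes, 6 rose (CG12200, CG2709, CG32088, CG8316, cona and hdm), 1 fell (okr) and 12 did not pass, with 8 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.000742, and adjusted p = 0.194 with an estimated correlation). hdm, a meiotic recombination gene, rose from 0.570 ± 0.291 to 10.5 ± 0.647 CPM and CG2709 (vilya) from 14.0 ± 0.127 to 38.8 ± 2.71 CPM. Of 10 testis genes, 3 rose and 7 did not pass, with 6 rises when adjusted over the list alone (camera adjusted p = 0.000869, and adjusted p = 0.323 with an estimated correlation). ocn rose from 0.159 ± 0.0687 to 6.65 ± 1.58 CPM and tomb, a gene of the testis meiotic arrest class, from 0.747 ± 0.194 to 7.82 ± 0.440 CPM. mia, of the same class, rose from 9.63 ± 1.46 to 17.6 ± 1.94 CPM (log2 fold change 0.87, edgeR adjusted p = 0.0191). The call of mia ended without EGFP KD 1 (adjusted p = 0.142), without L(3)mbt KD 1 (0.0569) and in a fit of the 4 libraries alone (0.0856).

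The 8 largest rises also held CG11052, at least 107-fold higher at 17.2 ± 0.142 CPM against no count in the control. Another was CG14516 (superdeath), which went from 2 counts to 33.4 ± 6.31 CPM, a ratio of 622.8 (95% counting interval 172.1 to 5148). Arpc3B, of the Arp2/3 actin-nucleating complex, hebe, CG12970 (cGlr1), a cGAS-like receptor, and Drsl5, a drosomycin-like peptide gene, had no count in the control and were at least 50.5-fold, 45.5-fold, 35.6-fold and 31.7-fold higher. Among the 8 largest falls were 3 neighbouring genes of the methuselah family of G protein-coupled receptors on 3L. mthl9 fell from 102.5 ± 2.24 to 16.8 ± 2.30 CPM (log2 fold change -2.61, SE 0.147, edgeR adjusted p = 1.41e-05). mthl10 fell from 5.54 ± 0.395 to 0.697 ± 0.259 CPM (-2.98, SE 0.449, edgeR adjusted p = 0.00256) and mth from 8.50 ± 0.915 to 2.01 ± 0.301 CPM (-2.07, SE 0.247, edgeR adjusted p = 0.000662). CG14608 (thw) fell from 33.0 ± 8.87 to 5.27 ± 0.899 CPM (-2.65, SE 0.434, edgeR adjusted p = 0.00412).

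Of 12 heat shock genes, 6 rose (Hsp23, Hsp26, Hsp27, Hsp67Ba, Hsp67Bc and Hsp68) and 6 did not pass, with 7 rises when adjusted over the list alone (camera adjusted p = 0.00355, and adjusted p = 0.323 with an estimated correlation). Hsp68 rose from 32.8 ± 1.63 to 76.9 ± 10.3 CPM and Hsp26 from 125.4 ± 7.97 to 245.9 ± 63.4 CPM. Hsp67Ba rose from 49.5 ± 5.31 to 89.7 ± 17.3 CPM, though not past the threshold without EGFP KD 2 (adjusted p = 0.0632). Of 6 apoptosis and p53 response genes, p53 rose from 37.0 ± 0.226 to 105.3 ± 11.6 CPM (log2 fold change 1.51, SE 0.130, edgeR adjusted p = 0.000101). Corp, a p53-regulated gene, rose from 0.934 ± 0.223 to 6.58 ± 0.226 CPM (2.80, SE 0.347, edgeR adjusted p = 0.000827), with 3 rises and 1 fall when adjusted over the list alone. Of 86 ribosomal protein genes, only RpS5b, from 154.0 ± 20 to 1290 ± 240.3 CPM (3.07, SE 0.173), and RpS19b, from 62.1 ± 5.80 to 176.4 ± 35.5 CPM (1.51, SE 0.153), passed, also when adjusted over the list alone. Both are second copies enriched in the germline, and how reads shared with RpS5a and RpS19a were counted is not given in the sources used here.

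Few members of the other lists passed. One of 7 dual-strand piRNA cluster factors rose, CG13741 (Boot), from 0.270 ± 0.0881 to 3.28 ± 0.898 CPM. So did 1 of 20 piRNA factors used by somatic cells, Hen1, the piRNA methyltransferase, from 11.3 ± 1.53 to 18.3 ± 0.812 CPM. In the follicle cell list 2 of 17 genes rose, eya (19.2 ± 0.412 to 32.3 ± 1.94 CPM) and Wnt4 (1.07 ± 0.0485 to 4.39 ± 0.272 CPM). In the neuronal list 1 of 10 rose, the calcium channel gene cac (5.35 ± 2.07 to 16.0 ± 2.66 CPM). In the hemocyte list it was 1 of 7, Cg25C (Col4a1, 218.8 ± 6.21 to 294.4 ± 3.395 CPM). In the muscle list 2 of 8 rose, Mlc2 (4.41 ± 0.825 to 14.8 ± 3.11 CPM) and Prm (7.07 ± 0.516 to 13.8 ± 0.194 CPM), and Act57B fell (29.4 ± 5.47 to 14.3 ± 2.62 CPM). The yolk protein gene Yp3 rose from 0.987 ± 0.955 to 7.71 ± 1.54 CPM (1 of 3 fat body genes), crb from 4.33 ± 0.791 to 16.8 ± 6.53 CPM (1 of 9 Hippo pathway target genes). AttD, an antimicrobial peptide gene without a count in the control, was at least 5.29-fold higher (1 of 3). Adjusted over the list alone, Hen1 did not pass, the fat body list had 2 rises and 1 fall, the antimicrobial list 2 rises and the sex determination list 1 rise, and the other counts here were the same. The 8 lists without a call in edgeR were the neural progenitor, LINT and dREAM repressor, cell cycle, siRNA and miRNA, insulator, ecdysone, JAK/STAT and sex determination genes. Their 91 tested members had 8 unadjusted p-values under 0.05, and DESeq2 called 1. Several of these single calls were lost with 1 library left out, where the log2 fold changes of Hen1 (0.56 to 0.86) and Cg25C (0.40 to 0.46) kept their sign. Left out in turn, the libraries ended the calls of Hen1 (all 4, adjusted p from 0.0824 to 0.268) and Cg25C (all 4, 0.0819 to 0.198). Without EGFP KD 1, EGFP KD 2 or L(3)mbt KD 2 the calls of eya (0.0758 to 0.124), Wnt4 (0.0600 to 0.0854) and Prm (0.0501 to 0.0970) ended. Act57B was lost without EGFP KD 2 (0.0929) or L(3)mbt KD 2 (0.0758), AttD without EGFP KD 1 (0.0667) or 2 (0.0684), and crb without EGFP KD 1 (0.0577). A fit of the 4 libraries alone also ended the calls of Hen1, Cg25C, eya, Prm, Act57B and AttD (adjusted p from 0.0505 to 0.142). With the gene-span trend removed eya (adjusted p = 0.0608) and Cg25C (0.0712) did not pass because their SE grew, from 0.172 to 0.220 and from 0.113 to 0.143, while log2 fold changes went from 0.75 to 0.71 and from 0.43 to 0.44.

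In all, 790 of 8244 tested genes were higher and 108 lower in L(3)mbt KD (edgeR, adjusted p under 0.05), and 611 and 20 of them changed at least 2-fold. In 293 of the 790 the control mean lay under 1 CPM. The number of genes higher was 511 without EGFP KD 1 and stayed within 1.5 times of the full count without any other library. The number lower changed more with the libraries used. It fell without EGFP KD 1, EGFP KD 2 or L(3)mbt KD 2 and grew without L(3)mbt KD 1. With DESeq2 164 genes were lower, and with the gene-span trend removed 222.

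The comparison of Lint-O KD with EGFP KD asks the same of Lint-O. Here too vas and aub rose, to 63.1 ± 12.4 CPM (log2 fold change 5.49, SE 0.213, edgeR adjusted p = 7.64e-06) and 41.1 ± 0.987 CPM (3.95, SE 0.199, edgeR adjusted p = 1.88e-05), from the control levels given above. cona rose to 53.6 ± 8.59 CPM (7.61, SE 0.379, edgeR adjusted p = 1.88e-05). CG11052, without a count in the control, was at least 65.1-fold higher at 10.5 ± 1.34 CPM (edgeR adjusted p = 3.66e-05). BigH1, the linker histone of germ cells and early embryos, went from 2 counts to 8.62 ± 1.45 CPM, a ratio of 160.7 (95% counting interval 44.1 to 1333, edgeR adjusted p = 7.53e-05).

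Of the 12 piRNA amplification factors 6 rose and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.690 with an estimated correlation). AGO3 reached 6.13 ± 1.56 CPM (log2 fold change 1.51, edgeR adjusted p = 0.00972) and qin 12.7 ± 0.364 CPM (2.33, edgeR adjusted p = 0.00984). tej reached 0.891 ± 0.0746 CPM, a ratio of 16.6 (95% counting interval 4.26 to 142.7, edgeR adjusted p = 0.0387), and CG9925, at 0.524 ± 0.149 CPM, was at least 3.25-fold higher (edgeR adjusted p = 0.0325). These 4 calls did not hold with fewer libraries. Those of tej and CG9925 were lost without any 1 of the 4 (log2 fold change then from 3.05 to 7.12 and from 6.06 to 6.63). AGO3 was lost without EGFP KD 1 (0.0693), EGFP KD 2 (0.0526) or Lint-O KD 2 (0.0769), and qin without EGFP KD 1 (0.0904), Lint-O KD 1 (0.0722) or Lint-O KD 2 (0.0654). krimp stood at 110.9 ± 11.9, spn-E at 168.6 ± 26.8, CG8920 at 66.3 ± 8.75, tud at 30.4 ± 8.36, BoYb at 25.97 ± 3.68 and squ at 14.97 ± 1.23 CPM, none past the test. Of 7 dual-strand cluster factors, cuff (6.39 ± 0.964 to 16.6 ± 0.473 CPM) and CG13741 (to 1.26 ± 0.149 CPM) rose, also when adjusted over the list alone. Both calls were lost without any 1 of the 4 libraries (adjusted p from 0.0583 to 0.164 and from 0.110 to 0.259). In a fit of the 4 libraries alone tej (0.0506) and CG13741 (0.0891) did not pass.

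Of 18 germline identity genes 9 rose and 9 did not pass, the same number when adjusted over the list alone (camera adjusted p = 9.21e-05, and adjusted p = 0.374 with an estimated correlation). They were the genes raised in L(3)mbt KD other than Pxt. exu, which acts in bicoid RNA localisation, rose from 2.27 ± 0.467 to 8.99 ± 0.487 CPM (log2 fold change 1.98, SE 0.238, edgeR adjusted p = 0.00103). gnu, a regulator of the embryo's first divisions, rose from 0.104 ± 0.147 to 3.72 ± 0.443 CPM (5.04, SE 0.679, edgeR adjusted p = 0.00203). Of 19 meiosis genes 6 rose and 13 did not pass, with 10 rises when adjusted over the list alone (camera adjusted p = 2.15e-05, and adjusted p = 0.132 with an estimated correlation). They were the 6 raised in L(3)mbt KD, among them hdm at 5.77 ± 0.219 CPM and CG2709 at 30.95 ± 3.50 CPM. Of 10 testis genes ocn (7.34 ± 0.301 CPM), tomb (9.49 ± 1.55 CPM) and mia (18.2 ± 1.31 CPM) rose and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000391, and adjusted p = 0.374 with an estimated correlation). mia was lost without any 1 of the 4 libraries (adjusted p from 0.0522 to 0.176).

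Other large rises were CG14516, at 7.13 ± 1.26 CPM a ratio of 132.9 (95% counting interval 36.4 to 1103), and CG7166, at 5.71 ± 3.34 CPM a ratio of 106.5 (29.1 to 884.9). Further ones were CG11674 (0.107 ± 0.00485 to 8.83 ± 0.339 CPM), CG33926 (Srg3, 0.333 ± 0.470 to 21.4 ± 6.33 CPM) and Vdup1 (0.104 ± 0.147 to 6.08 ± 0.00343 CPM). The largest falls after CG2662 itself held CG9521, from 398.5 ± 48.0 to 117.0 ± 14.2 CPM (log2 fold change -1.77, SE 0.184, edgeR adjusted p = 0.000445), and mthl9, to 47.3 ± 2.36 CPM (-1.12, SE 0.138, edgeR adjusted p = 0.00125). The fibroblast growth factor receptor gene htl fell from 8.06 ± 1.99 to 2.36 ± 0.00133 CPM and mthl10 to 1.60 ± 0.557 CPM. These 2 calls were lost without any 1 of the 4 libraries (adjusted p from 0.0652 to 0.246 and from 0.0976 to 0.282).

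One of 12 heat shock genes rose, Hsp68, to 59.2 ± 5.33 CPM (edgeR adjusted p = 0.00705), also when adjusted over the list alone (camera adjusted p = 0.274 for the list). Its call was lost without EGFP KD 1 (0.0546) or Lint-O KD 2 (0.0572). p53 rose to 54.1 ± 2.12 CPM (log2 fold change 0.55, SE 0.129, edgeR adjusted p = 0.0406), 1 of 6 in its list and 1 of 2 when adjusted over the list alone. Its call was lost without any 1 of the 4 libraries (0.126 to 0.233) and in a fit of those libraries alone (0.0520). Of 86 ribosomal protein genes RpS5b (353.7 ± 48.4 CPM) and RpS19b (113.5 ± 6.27 CPM) rose, also when adjusted over the list alone. The call of RpS19b was lost without EGFP KD 2 (0.0798) or Lint-O KD 1 (0.0736). In the other 16 lists edgeR called 0 of 168 tested members, with 17 unadjusted p-values under 0.05 and 2 calls by DESeq2. Adjusted over the list alone, they had 2 rises among fat body genes and 1 each among neuronal and antimicrobial genes.

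In all, 429 genes were higher and 21 lower in Lint-O KD (edgeR), 374 and 11 of them at least 2-fold, and in 183 of the 429 the control mean lay under 1 CPM. Without EGFP KD 1, EGFP KD 2, Lint-O KD 1 or Lint-O KD 2 in turn, 274, 278, 272 and 261 genes were higher and 5, 6, 4 and 3 lower. With DESeq2 34 genes were lower.

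The comparison of Lint-1 KD with EGFP KD asks the same of Lint-1. aub rose to 36.3 ± 4.998 CPM (log2 fold change 3.77, SE 0.198, edgeR adjusted p = 1.24e-05), vas reached 12.3 ± 0.270 CPM (3.14, SE 0.212, edgeR adjusted p = 3.03e-05) and cona 13.4 ± 4.45 CPM (5.61, SE 0.391, edgeR adjusted p = 3.66e-05). swa, hebe and yl, the last encoding the yolk protein receptor of the oocyte, had no count in the control and were at least 74.8-fold, 64.2-fold and 39.3-fold higher, at 12.1 ± 0.142, 10.4 ± 0.103 and 6.34 ± 2.15 CPM (edgeR adjusted p = 5.72e-05, 4.33e-05 and 0.000785). CG14516 went from 2 counts to 56.3 ± 3.06 CPM, a ratio of 1048 (95% counting interval 289.6 to 8655, edgeR adjusted p = 8.58e-06).

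Of the 12 piRNA amplification factors 5 rose and 7 did not pass, with 6 rises when adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.889 with an estimated correlation). AGO3 reached 6.56 ± 0.795 CPM (edgeR adjusted p = 0.00495), and tej 1.62 ± 0.213 CPM, a ratio of 30.3 (95% counting interval 8.06 to 255.4, edgeR adjusted p = 0.00722). qin reached 7.91 ± 2.96 CPM (edgeR adjusted p = 0.0375), a call lost without EGFP KD 1 (0.184), EGFP KD 2 (0.103) or Lint-1 KD 1 (0.198). CG9925 stood at 0.250 ± 0.0907 CPM (edgeR adjusted p = 0.0755). spn-E stood at 180.6 ± 32.4, krimp at 83.6 ± 23.2, CG8920 at 70.9 ± 4.74, BoYb at 24.2 ± 1.55, squ at 22.02 ± 0.0393 and tud at 19.4 ± 1.86 CPM, not past the test. tud passed without the low-count filter (log2 fold change -0.85, adjusted p = 0.0366). Of 7 dual-strand cluster factors CG13741 rose, to 2.03 ± 0.352 CPM, with 2 rises when adjusted over the list alone.

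Of 18 germline identity genes 9 rose and 9 did not pass, with 13 rises and 1 fall when adjusted over the list alone (camera adjusted p = 4.13e-06, and adjusted p = 0.235 with an estimated correlation). They were the 9 raised in Lint-O KD. bgcn reached 16.6 ± 1.05 CPM (log2 fold change 2.80, SE 0.270) and nos 5.52 ± 1.75 CPM, a ratio of 101.4 (95% counting interval 27.8 to 842.9). Of 19 meiosis genes 7 rose, the 6 above and nod, and 12 did not pass, with 7 rises when adjusted over the list alone (camera adjusted p = 8.19e-05, and adjusted p = 0.181 with an estimated correlation). hdm reached 21.1 ± 1.01 CPM (5.21, SE 0.308) and CG2709 42.9 ± 3.12 CPM (1.62, SE 0.156). Of 10 testis genes ocn (3.53 ± 0.40 CPM), tomb (3.54 ± 0.120 CPM) and mia (21.3 ± 1.55 CPM) rose and 7 did not pass, with 6 rises when adjusted over the list alone (camera adjusted p = 0.000701, and adjusted p = 0.248 with an estimated correlation). mia was lost without EGFP KD 1 (adjusted p = 0.0514).

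Further large rises were CG11052 and Arpc3B, at least 41.0-fold and 34.9-fold higher at 6.60 ± 0.520 and 5.63 ± 0.334 CPM, CG11674, at 49.4 ± 3.37 CPM, and BigH1, at 19.0 ± 0.0415 CPM a ratio of 353.9 (95% counting interval 97.6 to 2928). The largest falls were CG8213 (flz), from 7.64 ± 1.48 to 1.27 ± 0.311 CPM (log2 fold change -2.58, SE 0.416, edgeR adjusted p = 0.00411), and Lint-1 itself. Cyp6d5, a cytochrome P450 gene, fell from 160.0 ± 3.13 to 51.6 ± 15.9 CPM (-1.63, SE 0.189, edgeR adjusted p = 0.000646), and CG9521 fell to 150.1 ± 27.5 CPM (-1.41, SE 0.182, edgeR adjusted p = 0.00125). Falls of CG14608 (-1.90, edgeR adjusted p = 0.0206) and Idgf1 (-1.42, edgeR adjusted p = 0.00757) were lost without EGFP KD 2 (0.0921) and without Lint-1 KD 2 (0.0684).

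Of 12 heat shock genes 7 rose, the 6 raised in L(3)mbt KD and Hsp70Bc, and 5 did not pass, with 8 rises when adjusted over the list alone (camera adjusted p = 0.000119, and adjusted p = 0.235 with an estimated correlation). Hsp70Bc belongs to a family of near-identical copies, so its count is uncertain. Hsp68 reached 84.7 ± 1.75 CPM, Hsp26 280.5 ± 2.37 CPM, and Hsp23 rose from 67.1 ± 0.372 to 166.8 ± 18.4 CPM (log2 fold change 1.31, SE 0.174, edgeR adjusted p = 0.00141). p53 rose to 72.3 ± 2.83 CPM (0.96, SE 0.129, edgeR adjusted p = 0.00148) and Corp to 5.37 ± 1.22 CPM (2.51, SE 0.348, edgeR adjusted p = 0.00182), 2 of 6 in their list, with 3 rises and 1 fall when adjusted over the list alone. Of 86 ribosomal protein genes RpS5b (912.2 ± 30.5 CPM), RpS19b (234.5 ± 5.22 CPM) and RpS10a rose and RpL35 fell, with 2 rises when adjusted over the list alone. The list as a whole was lower than other genes (camera adjusted p = 0.0198, and adjusted p = 0.975 with an estimated correlation; median log2 fold change -0.06). The median difference of these genes between the 2 libraries of a group was 0.16 in EGFP KD and -0.01 in Lint-1 KD (log2, replicate 1 minus replicate 2), more than this shift in the control. The fall of RpL35 (-0.47, edgeR adjusted p = 0.0369) was lost with upper-quartile scaling (0.0548) and without any 1 of the 4 libraries (0.0917 to 0.315).

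Elsewhere single members rose: eya, to 51.5 ± 9.73 CPM (log2 fold change 1.42, SE 0.172, edgeR adjusted p = 0.000846, 1 of 17 follicle genes), and crb, to 18.6 ± 5.96 CPM (1 of 9 Hippo pathway target genes). In the muscle list Mlc2 rose to 22.9 ± 2.34 CPM (2.37, SE 0.234, edgeR adjusted p = 0.000247), while Act57B fell to 13.4 ± 2.01 CPM. Appl (1 of 10 neuronal genes), mira (1 of 6 neural progenitor genes), Cg25C (1 of 7 hemocyte genes), the mitotic kinase gene aur (1 of 23 cell cycle genes), Vago (1 of 10 siRNA and miRNA genes) and Ibf2 (1 of 10 insulator genes) rose with adjusted p between 0.00969 and 0.0471. Adjusted over the list alone, aur did not pass, follicle genes had 2 rises, fat body genes 1, and antimicrobial genes 2 rises and 1 fall, the other counts here being the same. The calls of mira (adjusted p from 0.0511 to 0.162), aur (0.104 to 0.298), Vago (0.0616 to 0.208) and Ibf2 (0.0529 to 0.177) were lost without any 1 of the 4 libraries. That of aur was also lost with DESeq2 size factors (0.0511). Appl (0.0797 to 0.134) and Cg25C (0.0660 to 0.101) were lost without EGFP KD 1, EGFP KD 2 or Lint-1 KD 2, and Act57B without EGFP KD 2 (0.0746) or Lint-1 KD 2 (0.101). In the 7 lists without a call, which held the somatic piRNA, fat body, LINT and dREAM repressor, antimicrobial, ecdysone, JAK/STAT and sex determination genes, edgeR called 0 of 68 tested members, with 13 unadjusted p-values under 0.05 and 2 calls by DESeq2.

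In all, 693 genes were higher and 103 lower in Lint-1 KD (edgeR), 525 and 27 of them at least 2-fold, and in 258 of the 693 the control mean lay under 1 CPM. Without EGFP KD 1, EGFP KD 2, Lint-1 KD 1 or Lint-1 KD 2 in turn, 445, 422, 439 and 414 genes were higher and 36, 16, 40 and 11 lower. With DESeq2 191 genes were lower, and with the gene-span trend removed 204.

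The genes raised by the 3 knockdowns overlapped. Of the 429 raised in Lint-O KD, 414 (96.5%) were also raised in L(3)mbt KD, where 41.1 would overlap if the lists were independent, and they made up 52.4% of the 790. Of the 693 raised in Lint-1 KD, 586 (84.6%) were raised in L(3)mbt KD (66.4 if independent), which is 74.2% of the 790. Lint-O KD and Lint-1 KD shared 370 (36.1 if independent), 86.2% and 53.4% of their raised genes. Among 906 genes raised in any knockdown, 264 were raised in only 1 and 364 in all 3, including vas, aub, AGO3, tej, qin, cona, hdm, nos and swa. A further 222 were raised in L(3)mbt KD and Lint-1 KD but not called in Lint-O KD, 154 in L(3)mbt KD alone, 101 in Lint-1 KD alone, 50 in L(3)mbt KD and Lint-O KD, and 9 in Lint-O KD alone. Fewer lowered genes were shared: 7 in L(3)mbt KD and Lint-O KD (0.275 if independent), 37 in L(3)mbt KD and Lint-1 KD (1.35) and 3 in Lint-O KD and Lint-1 KD (0.262), with 3 of 188 lower in all 3. No gene was called in opposite directions by edgeR in any pair. At an unadjusted p under 0.05, 9, 2 and 17 genes were, and DESeq2 called 0, 1 and 0, in the pairs L(3)mbt with Lint-O, L(3)mbt with Lint-1, and Lint-O with Lint-1.

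Because the 3 comparisons share their control libraries, all 8 libraries, the control included, were simulated as unchanged from the control means. The simulated comparisons shared their simulated control, not the real control libraries. Libraries were drawn independently, without the correlated replicate differences of the data, and genes without a count in the control could not rise. The simulated overlap therefore does not measure what the real control libraries contribute. In 50 simulations the overlap of raised genes averaged 0.02 and reached 1, and that of lowered genes was 0. Across genes, which are not independent replicates, fold changes correlated at 0.84 (L(3)mbt with Lint-O), 0.90 (L(3)mbt with Lint-1) and 0.77 (Lint-O with Lint-1), where the simulations gave 0.50 in each case. The share of genes with the same sign was 68.2%, 81.7% and 66.6%, against 66.6%, 66.5% and 66.6% in the simulations. The covariances of 0.473, 0.616 and 0.416 exceeded the simulated 0.0422, 0.0420 and 0.0421 by 0.431, 0.574 and 0.374. Neither the simulated nor the independent value holds both the shared controls and real effects, and part of the excess overlap may come from the shared controls. With the controls split after these results were seen, so that each knockdown of a pair was tested against a different control library, the overlaps are given as means of both ways round. L(3)mbt with Lint-O shared 251 raised genes (17.1 if independent), L(3)mbt with Lint-1 344.5 (26.9) and Lint-O with Lint-1 220 (14.1), and 2, 4 and 2 lowered genes were shared. Fold changes fitted by edgeR then correlated at 0.62, 0.70 and 0.58 over 8494 genes and had the same sign in 56.5%, 69.6% and 54.9% of them. The correlations and signs with shared controls were of differences of mean log CPM over 8244 genes, so the 2 sets of values do not measure the effect of the split.

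**Figure D3:**
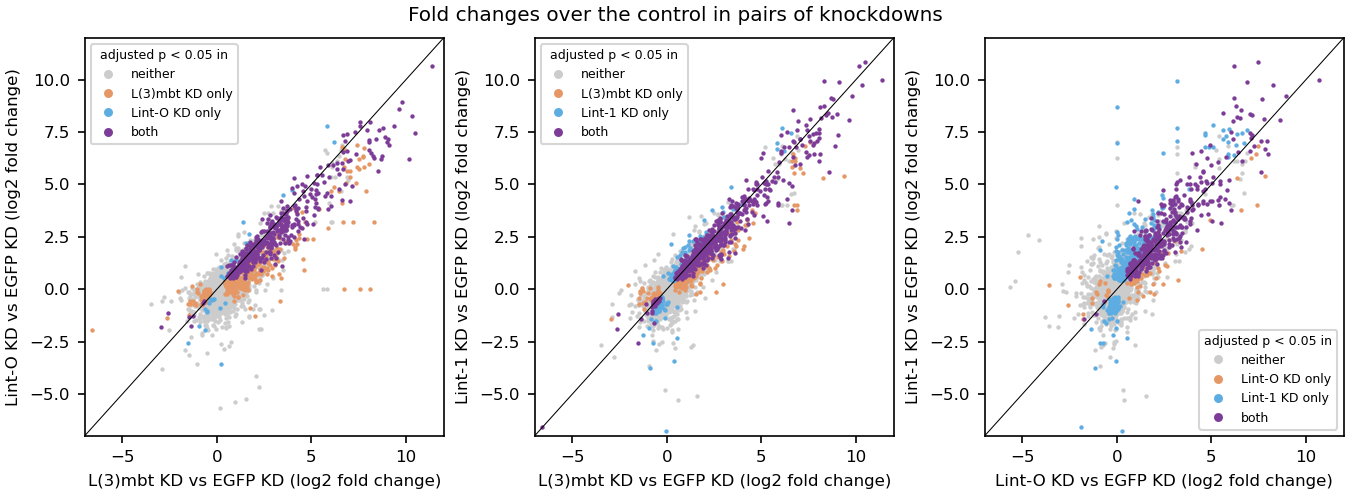
Log2 fold change against EGFP KD in pairs of knockdowns, with 1 point per tested gene and axes from -7 to 12; colours mark genes with an edgeR adjusted p under 0.05 in neither, 1 or both knockdowns. Raised genes lie along the diagonal, and fitted values of genes without a count in the control depend on the prior count. Across all tested genes, differences of mean log CPM, which are not the values plotted, correlated at 0.84, 0.90 and 0.77.

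The direct comparison of Lint-O KD with L(3)mbt KD asks where these knockdowns differ, and the control libraries do not enter the contrast. Beyond the targets, hebe and the oocyte gene swa were lower in Lint-O KD. hebe stood at 0.472 ± 0.222 against 7.33 ± 0.106 CPM (log2 fold change -3.94, SE 0.353, edgeR adjusted p = 0.00424) and swa at 1.13 ± 0.557 against 9.06 ± 0.434 CPM (-2.999, SE 0.339, edgeR adjusted p = 0.0141). The ryanodine receptor gene RyR (-3.30, SE 0.553, edgeR adjusted p = 0.0385) and CG10132 (-2.85, SE 0.465, edgeR adjusted p = 0.0365) were also lower. Higher in Lint-O KD were mth, at 8.07 ± 1.34 against 2.01 ± 0.301 CPM (2.00, SE 0.247, edgeR adjusted p = 0.0141), mthl9, at 47.3 ± 2.36 against 16.8 ± 2.30 CPM (1.49, SE 0.143, edgeR adjusted p = 0.00405), and l(3)mbt (1.14, SE 0.102, edgeR adjusted p = 0.00365). CG2662 was lower (-3.78, SE 0.263, edgeR adjusted p = 0.00133) and Lint-1 did not pass (-0.02, edgeR adjusted p = 0.956).

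Germline identity genes were lower in Lint-O KD as a list, with bgcn and swa called and 8 lower when adjusted over the list alone (camera adjusted p = 2e-05, and adjusted p = 0.696 with an estimated correlation). Heat shock genes were lower as a list with 0 of 12 called by edgeR and 6 lower when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.696 with an estimated correlation). Ribosomal protein genes were higher as a list (camera adjusted p = 0.0103, and adjusted p = 0.974 with an estimated correlation; median log2 fold change 0.09), while the 1 member called, RpS5b, was lower. The shift is smaller than the median difference of these genes between the 2 libraries of a group, 0.26 in Lint-O KD and -0.29 in L(3)mbt KD (log2, replicate 1 minus replicate 2). vas and p53 were lower, 1 member each of their lists. The other 20 lists had no call by edgeR among 216 tested members, with 38 unadjusted p-values under 0.05 and 11 calls by DESeq2.

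In all, 3 genes were higher and 55 lower in Lint-O KD than in L(3)mbt KD (edgeR). Leaving out L(3)mbt KD 1 gave 35 and 83, L(3)mbt KD 2 gave 2 and 9, and either Lint-O library gave 0 and 1, with DESeq2 calling 20 and 226 on all libraries. Without Lint-O KD 1 or Lint-O KD 2 in turn the calls of l(3)mbt (adjusted p = 0.0706 and 0.0564), mthl9 (0.0659 and 0.0564), hebe (0.0659 and 0.0576), swa (0.145 and 0.0564), mth (0.104 and 0.127), RyR (0.382 and 0.256) and CG10132 (0.206 and 0.203) were lost. Those of mth (0.0837), RyR (0.128) and CG10132 (0.139) were also lost without L(3)mbt KD 2.

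The direct comparison of Lint-1 KD with L(3)mbt KD called 6 genes, of which 2 were the targets and the others lay in germline genes and the methuselah locus. vas was lower in Lint-1 KD, at 12.3 ± 0.270 against 123.5 ± 1.86 CPM (log2 fold change -3.32, SE 0.175, edgeR adjusted p = 0.000113), as was cona, at 13.4 ± 4.45 against 105.3 ± 17.4 CPM (-2.98, SE 0.248, edgeR adjusted p = 0.00205). mth, at 9.66 ± 0.185 against 2.01 ± 0.301 CPM (2.26, SE 0.246, edgeR adjusted p = 0.00978), and mthl9, at 45.3 ± 2.26 against 16.8 ± 2.30 CPM (1.43, SE 0.143, edgeR adjusted p = 0.00718), were higher. l(3)mbt was higher (0.99, SE 0.102, edgeR adjusted p = 0.00757), Lint-1 lower (-2.85, SE 0.166, edgeR adjusted p = 0.000138), and CG2662 did not pass (0.0085). As lists, piRNA amplification factors (camera adjusted p = 0.00504, 1 of 12 called and 2 lower when adjusted over the list alone) and germline identity genes (0.0196, 0 of 18 called by edgeR and 2 lower when adjusted over the list alone) were lower. Heat shock genes (0.0196) and neural progenitor genes (0.0425) were higher with 0 calls, also when adjusted over the list alone. All 4 had an adjusted p = 0.717 with an estimated correlation. The 22 lists without a call by edgeR held 307 tested members, with 28 unadjusted p-values under 0.05 and 3 calls by DESeq2.

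The counts of 3 genes higher and 3 lower (edgeR) became 3 and 6 with upper-quartile scaling, 3 and 15 with the gene-span trend removed, and 12 and 43 with DESeq2. Without L(3)mbt KD 1 they were 3 and 5, without L(3)mbt KD 2 or Lint-1 KD 2 they were 1 and 3, and without Lint-1 KD 1 they were 0 and 3. The calls of l(3)mbt and mth were lost without L(3)mbt KD 2 (adjusted p = 0.0758 and 0.0882), Lint-1 KD 1 (0.128 and 0.108) or Lint-1 KD 2 (0.130 for both), and that of mthl9 without Lint-1 KD 1 (0.0762). In a fit of these 4 libraries alone none of the 3 passed (0.0917, 0.0628 and 0.0762).

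The direct comparison of Lint-1 KD with Lint-O KD found yl, hebe and swa higher in Lint-1 KD. yl stood at 6.34 ± 2.15 CPM against 2 counts in Lint-O KD, a ratio of 122.6 (95% counting interval 33.6 to 1018, edgeR adjusted p = 0.00852). hebe (log2 fold change 4.44, SE 0.351, edgeR adjusted p = 0.00148) and swa (3.41, SE 0.338, edgeR adjusted p = 0.00497) were higher too, as was dao (4.09, SE 0.711, edgeR adjusted p = 0.0337). vas was lower, at 12.3 ± 0.270 against 63.1 ± 12.4 CPM (-2.36, SE 0.170, edgeR adjusted p = 0.000442), along with CG8745 (-2.19, SE 0.286, edgeR adjusted p = 0.00902), CG7166 (-2.81, SE 0.543, edgeR adjusted p = 0.0490) and the non-coding RNA CR31451 (-2.19, SE 0.399, edgeR adjusted p = 0.0395). CG2662 was higher (3.78, SE 0.263, edgeR adjusted p = 0.000442), Lint-1 lower (-2.83, SE 0.166, edgeR adjusted p = 0.000296), and l(3)mbt did not pass (-0.15, edgeR adjusted p = 0.462).

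In the germline identity list bgcn, nos and swa were higher in Lint-1 KD (5 higher and 1 lower when adjusted over the list alone), and in the meiosis list CG32088 and hdm were higher and cona lower (6 and 2 when adjusted over the list alone). In the heat shock list Hsp23 was higher (7 when adjusted over the list alone, camera adjusted p = 8.99e-05, and adjusted p = 0.498 with an estimated correlation). Ribosomal protein genes were lower as a list (camera adjusted p = 0.00903, and adjusted p = 0.85 with an estimated correlation; median log2 fold change -0.11, against 0.26 between the 2 libraries of Lint-O KD) although RpS19b and RpS5b were higher. tomb was lower and eya and Mlc2 higher, 1 member each of their lists. In the 16 lists without a call by edgeR, 156 members had 21 unadjusted p-values under 0.05 and DESeq2 called 8.

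In all, 75 genes were higher and 22 lower in Lint-1 KD than in Lint-O KD (edgeR). Leaving out Lint-1 KD 1, Lint-1 KD 2, Lint-O KD 1 or Lint-O KD 2 gave 18, 13, 3 and 7 higher and 7, 2, 2 and 2 lower, while DESeq2 called 200 and 95 on all libraries. The calls of dao (adjusted p from 0.122 to 0.318), CG7166 (0.110 to 0.390), CG8745 (0.0948 to 0.124) and CR31451 (0.0788 to 0.312) were lost without any 1 of the 4 libraries. The call of yl was lost without Lint-1 KD 1 (0.0641), Lint-O KD 1 (0.101) or Lint-O KD 2 (0.121), and that of swa without Lint-O KD 1 (0.0702). CG7166 was also lost with the stricter low-count filter (0.0519).

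Among the 364 genes raised in all 3 knockdowns, 26 were lower and 0 higher in Lint-O KD than in L(3)mbt KD (edgeR, with 129 and 10 at an unadjusted p under 0.05, and 60 and 0 by DESeq2). In Lint-1 KD 2 were lower and 0 higher than in L(3)mbt KD (61 and 20 unadjusted, 17 and 1 by DESeq2), and 33 were higher and 4 lower than in Lint-O KD (108 and 42 unadjusted, 45 and 11 by DESeq2). Most edgeR calls in the 2 comparisons with Lint-O KD were lost when either Lint-O library was left out.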

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

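The tests of library depth, germ cells, shared control libraries, a weaker knockdown, and gene span among directly tested genes were chosen after the results they bear on had been seen, while the test of span among replicate differences was set beforehand. The share of reads that fell in no annotated gene was 18.51% in L(3)mbt KD 2, above the 16.25% and 15.63% of the control libraries, in a line of the count table that no comparison uses.

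Within each group the 2 libraries differed along gene span: the Spearman correlation across genes of their difference with span was -0.57 in EGFP KD, 0.50 in L(3)mbt KD, -0.58 in Lint-O KD and 0.31 in Lint-1 KD. Library depth as the cause of this trend predicts the same sign as the depth difference in every group, and the sign matched in 2 of 4. The differences were also correlated between groups, and gene span bias was argued against as the whole cause of that correlation alone: with the span trend removed from 6183 genes its median absolute value was 0.464, against 0.605 before. What caused the trend with span stays open, and a candidate explanation for the correlation is a shared step that handled libraries of different groups together, since the differences of EGFP KD and Lint-O KD ran with each other (0.62) and against those of L(3)mbt KD (-0.74 and -0.59). No biological explanation was tested.

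Of 18 tested germline identity genes 10, 9 and 9 rose in L(3)mbt, Lint-O and Lint-1 KD. The list tests did not pass with an estimated correlation (camera adjusted p = 0.194, 0.374 and 0.235) but passed with fry (fry adjusted p = 0.00124, 0.0104 and 0.00360). Germ cells in the knockdown cultures would bring their abundant transcripts with vas, which lay between 12.1 and 124.8 CPM. Of the 24 germline list members with an entry, 14 lay under 1 CPM in the control; 6 of these stayed under 1 CPM in every knockdown library, osk reaching 0.105 CPM and otu and BicC having no count, and 8 reached it, up to 12.2 CPM for swa, which does not decide for or against germ cells. Deviations of single control libraries as the whole cause of the overlap of raised genes were argued against. With a different control library for each knockdown of a pair, every pair still shared more raised genes than independent lists would. A deviation common to both control libraries would enter both sides of this split, which therefore does not speak to it. A share of germ cells of 1 fixed make-up would move germline genes together. In Lint-1 KD against Lint-O KD, edgeR called 3 of 18 germline identity genes higher (bgcn, nos and swa) and 0 lower. Of 19 meiosis genes 2 were higher and 1 (cona) lower, and of 12 piRNA amplification factors 0 were higher and 1 (vas) lower. These called genes went both ways, which such a share as the whole cause would not give. Most calls of this comparison were lost when either Lint-O library was left out, and that of swa was lost without Lint-O KD 1. Some vas reads could also belong to solo. The argument against a share of fixed make-up is therefore weak and rests on few genes. A response within the somatic cells and germ cells whose make-up differs between knockdowns stay open as candidate explanations.

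Among the 370 genes raised in both Lint-1 KD and Lint-O KD, 118 differed between them in the direct test adjusted over these genes, 86 higher and 32 lower in Lint-1 KD. If the knockdown of one were weaker at every shared target, these calls would go 1 way, but for the 5% that may be false, and 32 is more than that (one-sided exact binomial p = 2.41e-15, which treats genes as independent although they may be regulated together). With the replicate block 52 were higher and 15 lower (one-sided exact binomial p = 8.81e-07), and with DESeq2 79 and 25 (4.57e-11). The test also asked for this excess without each library in turn. Calls then went both ways each time, but the excess did not pass without Lint-1 KD 2, where fewer calls remained. The condition was therefore not met in full, and the test does not decide whether one knockdown was weaker at every shared target. One weaker at most of them stays open as well. Gene span bias would remove the calls with the trend, and 116 were left (85 and 31), which argues against it as the whole cause. How much protein was left in each knockdown, and whether the shared genes depend on the proteins to different degrees, stay open too.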

How the results depend on the processing

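The crossed replicate numbers, the removal of the gene-span trend and the split of the control libraries were chosen after seeing the data. No value of a named gene reversed its direction where it was called in the reported or the alternative fit. Of 2402 alternative values for 185 values of named genes, 2166 kept their side of the threshold, 222 no longer passed and 14 newly passed. Sign changes of values called in neither fit were counted among those kept. Of 222 alternative values of counts, 104 lay within 1.5 times of the reported count. Counts of raised genes against the control stayed within that range under both scalings, DESeq2, both filters and the fit of 4 libraries, and DESeq2 also called 894 of the 898, 449 of the 450 and 793 of the 796 genes called in L(3)mbt, Lint-O and Lint-1 KD. Genes lower and genes called between knockdowns moved with most settings, and except where fewer libraries were used the cause was not tested. With 1 library left out, the lone library of a group is assumed to vary like the other groups. At these depths and 2 libraries per group, 2-fold changes were recovered less often than 4-fold ones in simulated data (81% and 95% for L(3)mbt KD).

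Leaving out 1 library at a time gave 511 to 776 genes higher and 20 to 432 lower in L(3)mbt KD, 261 to 278 and 3 to 6 in Lint-O KD, and 414 to 445 and 11 to 40 in Lint-1 KD. Between Lint-O KD and L(3)mbt KD it gave 0 to 35 higher and 1 to 83 lower, between Lint-1 KD and L(3)mbt KD 0 to 3 and 3 to 5, and between Lint-1 KD and Lint-O KD 3 to 18 and 2 to 7. The DESeq2 test called 164 genes lower in L(3)mbt KD, 34 in Lint-O KD and 191 in Lint-1 KD, and 20 higher and 226 lower, 12 and 43, and 200 and 95 in the 3 direct comparisons in that order. Without the low-count filter these were 168, 32 and 277, and 26 and 255, 12 and 44, and 244 and 146. A fit of the 4 libraries compared called 19 genes lower in L(3)mbt KD, 32 lower in Lint-O KD than in L(3)mbt KD, 0 higher in Lint-1 KD than in L(3)mbt KD, and 237 higher and 174 lower in Lint-1 KD than in Lint-O KD. Upper-quartile scaling gave 6 genes lower in Lint-1 KD than in L(3)mbt KD. At least 2-fold lower were 20, 11 and 27 genes in L(3)mbt, Lint-O and Lint-1 KD, and 6 were lower in both L(3)mbt KD and Lint-1 KD. With the gene-span trend removed 222 genes were lower in L(3)mbt KD and 204 in Lint-1 KD, 7 higher and 102 lower in Lint-O KD than in L(3)mbt KD, 15 lower in Lint-1 KD than in L(3)mbt KD, and 118 higher and 50 lower in Lint-1 KD than in Lint-O KD. The overlap of lowered genes was then 77 for L(3)mbt with Lint-1 and 6 for Lint-O with Lint-1. With the control libraries split between the knockdowns of a pair (mean of both ways round), 251 raised and 2 lowered genes were shared by L(3)mbt with Lint-O, 344.5 and 4 by L(3)mbt with Lint-1, and 220 and 2 by Lint-O with Lint-1, from fewer libraries. With an estimated correlation 0 gene lists passed in any of the 6 comparisons (5, 4, 6, 3, 4 and 2 with the preset one). The meiosis list lost its calls too, although its estimated correlation was -0.03, so these losses alone do not show that list members were correlated. Against the control, fry kept the piRNA amplification, germline identity, meiosis and testis lists in all 3 knockdowns (fry adjusted p from 0.000351 to 0.0136). It lost the ribosomal protein list in Lint-1 KD (0.874), and it passed 0, 0 and 1 lists in the 3 direct comparisons.

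The replicate numbers were not shown to pair the libraries: correlations of the replicate differences between groups ran from -0.74 to 0.71. The replicate block gave 636, 333 and 553 genes higher and 47, 6 and 40 lower in L(3)mbt, Lint-O and Lint-1 KD. In the direct comparisons it gave 2 and 8 for Lint-O with L(3)mbt, 1 and 3 for Lint-1 with L(3)mbt, and 24 and 9 for Lint-1 with Lint-O. Of the calls without the block, 679 of 898, 339 of 450, 591 of 796, 10 of 58, 4 of 6 and 33 of 97 were also made with it, and overlaps of lowered genes were 3 (L(3)mbt with Lint-O) and 12 (L(3)mbt with Lint-1). A crossed replicate block, with the numbers of L(3)mbt KD and Lint-1 KD swapped, gave 1342 genes higher and 1186 lower in L(3)mbt KD, 644 and 172 in Lint-O KD, 1300 and 1232 in Lint-1 KD, 572 and 658, 60 and 173, and 788 and 961 in the direct comparisons, so that more genes were lower than higher in Lint-1 KD against Lint-O KD where more had been higher without the block, 0 gene lists past the threshold between Lint-1 KD and L(3)mbt KD and 4 in Lint-1 KD against the control, and overlaps of 94 lowered genes (L(3)mbt with Lint-O), 1004 raised and 759 lowered (L(3)mbt with Lint-1), and 563 raised and 68 lowered (Lint-O with Lint-1).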

Other observations

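The tests on chromosome 4 and on neighbouring genes were chosen after the results had been seen, and the test on nested genes was set before its result. Chromosome 4, the small and largely heterochromatic chromosome, held many genes raised in L(3)mbt KD: 22 of its 80 tested genes rose (27.5%), against 9.48% elsewhere (Fisher's exact p = 4.08e-06, two-sided, adjusted p = 7.34e-05 over 18 tests of chromosome arms). Among them were Syt7, a synaptotagmin gene, with a log2 fold change of 5.22 (SE 0.420, edgeR adjusted p = 6.73e-05), CG11155 (3.61, SE 0.283, edgeR adjusted p = 6.05e-05) and yellow-h (3.37, SE 0.236, edgeR adjusted p = 3.65e-05), named after their values were seen. In Lint-O KD 14 of the 80 rose (17.5%, against 5.12% elsewhere, adjusted p = 0.000541). In Lint-1 KD 11 rose (13.8%, against 8.40%), which did not pass (Fisher's exact p = 0.102, adjusted p = 0.459). Whether the knockdowns differ in this was not tested.

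Genes on chromosome 4 are longer, with a median span of 8406 bp against 2727 bp elsewhere. Draws of 80 genes of like span and level from the other chromosomes gave 9.70 raised genes on average and at most 21 in L(3)mbt KD, and 4.40 and at most 13 in Lint-O KD, both with a permutation p of 1e-04, the smallest that 10000 draws can give. In Lint-1 KD they gave 8.58 on average (permutation p = 0.24). These draws and Fisher's test treat genes as independent, although genes of 1 chromosome may shift together, and do not measure the spread between libraries. Leaving out 1 library at a time left 17 to 21 raised genes on chromosome 4 in L(3)mbt KD. In Lint-O KD it left 9 without EGFP KD 1, 11 without EGFP KD 2 and 10 without either Lint-O library. As a hypothesis, genes on chromosome 4 may be held down by L(3)mbt and Lint-O more often than genes of like span and level elsewhere. It rests on 22 and 14 raised genes, and most of the 14 were among the 22, called against the same control libraries. The results of L(3)mbt KD and Lint-O KD are therefore not independent.

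The methuselah genes that fell in L(3)mbt KD lie inside Ptpmeg, a protein tyrosine phosphatase gene (dm6, 3L, 328097 to 356050), which itself rose. Ptpmeg went from 46.4 ± 2.67 to 85.6 ± 7.65 CPM in L(3)mbt KD (n = 2, log2 fold change 0.88, SE 0.135, edgeR adjusted p = 0.00277) and to 80.0 ± 7.94 CPM in Lint-1 KD (0.78, SE 0.135, edgeR adjusted p = 0.00600), and stood at 58.9 ± 2.74 CPM in Lint-O KD (0.34, edgeR adjusted p = 0.290). Within it lie mthl9 (329822 to 332309), mthl10 (332801 to 342915) and mth (343378 to 346957). mthl9 fell in all 3 knockdowns, with a log2 fold change of -1.18 (SE 0.139, edgeR adjusted p = 0.000713) in Lint-1 KD. mthl10 had -1.44 in Lint-1 KD (edgeR adjusted p = 0.0549), and mth had -0.07 in Lint-O KD (edgeR adjusted p = 0.986) and 0.19 in Lint-1 KD (edgeR adjusted p = 0.648). Of the genes on either side, Atac3 did not pass in L(3)mbt KD (0.06, edgeR adjusted p = 0.855) and Cdc5 fell (-0.43, edgeR adjusted p = 0.0369). Ptpmeg, Atac3 and Cdc5 were chosen after their values had been seen.

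A general fall of genes nested in a raised gene was not detected. Without Ptpmeg, 55 genes inside a raised gene in L(3)mbt KD had a median log2 fold change 0.0317 above that of 395 genes inside a gene that was not called (0.08 and 0.04, one-sided permutation p for lower values 0.664, 10000 permutations). The difference was 0.0973 in Lint-O KD (permutation p = 0.926) and -0.0353 in Lint-1 KD (permutation p = 0.310). Raised genes were not shown to cluster along the chromosomes. In L(3)mbt KD 90 pairs of adjacent tested genes were both raised against 75.7 in shuffled orders (permutation p = 0.0452), in Lint-1 KD 70 against 58.0 (0.0569) and in Lint-O KD 28 against 22.4 (0.130), and the smallest p adjusted over the 3 tests was 0.0853.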
